A study of Mus musculus with 2 samples.

How the data were processed

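Single-cell RNA libraries were made from the retinas of 2 female littermate mice at postnatal day 0, per the labels. One animal carried a conditional Foxp1 transgene without Cre (control) and the other carried the same transgene with Six3-Cre, which is active in retinal progenitors (Foxp1 cTG, conditional transgenic). The 2 retinas of each animal were pooled and dissociated enzymatically for 35 min, strained through a 40 µm mesh and loaded for 10x Genomics 3' gene expression, per the labels' protocols. Each genotype therefore had 1 library from 1 animal, and no replicate check of any difference was possible.

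The deposited expression table held score values, not counts, for 3000 genes in 7994 cells. Cell Ranger 3.1.0, Seurat 4.0.3 and the mm10 mouse build are named in the submitters' processing notes. The normalization function, the filters on cells and genes and the regressed covariates were not given in the sources used here. The values themselves had a mean of 0 for each gene over the cells of both libraries together, negative values, and a highest value of 17.02, near the square root of the cell number divided by 30 (16.32), which the model below applies as a limit before centring. These are the properties of Pearson residuals from a regularised negative binomial model fitted to the merged cells. Such values are differences from a fitted mean and have no true zero, so folds cannot be taken from them directly. A second deposited table gave the library, the cell class and a DoubletFinder call of each cell, per the file headers.

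UMI counts (unique molecular identifiers, 1 per captured transcript) were recovered by inverting that model. The values of cells with 0 UMIs lay on 2 coordinates shared by all genes, which held 99.97% of their variation. One coordinate acted as sequencing depth and the other as a removed linear covariate. That covariate had a Pearson correlation over cells of -0.889 with the G2/M score minus the S score computed from the recovered counts. A gene counted as recovered if at least 95% of its values below the limit, at 0 UMIs and at 1 or more alike, lay within 0.1 of a whole number, as for 2445 genes (81.5%). In 2128 of them every value of 1 or more UMIs did. Of the 3036889 values of 1 or more UMIs below the limit in recovered genes, 99.8% lay within 0.1 of a whole number, where evenly spread values would give 20%. Genes were fitted towards whole numbers and kept by this same criterion. The share therefore describes the kept genes and does not test the recovery. Values at the limit (0.69% of the nonzero ones) gave the lowest count they allow. A level is called a lower bound where more than 5% of a gene's nonzero cells in either library were at the limit. A further 441 rare genes reached the limit with 1 UMI and gave detection only, and 114 mostly abundant genes were not recovered. For the latter only mean residuals are given. The recovered genes summed to 8120975 UMIs, which is the part of each library these genes hold and not its full depth.

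The recovery was tested on simulated data, with 800 genes drawn at the depth of the progenitor comparison. The genes were drawn from those already solved, and their values were simulated from the same model with its fitted parameters. The simulation therefore tests the inversion and not whether the deposited values follow that model. Counts came back for 771 genes, and 100.0% of their nonzero counts below the limit equalled the simulated ones. The rule of size used for named genes passed 0 of 421 simulated genes at a fold of 1.0, 22 of 47 at 1.5, 51 of 52 at 2.0 and 39 of 39 at 3.0. This simulation holds counting error and the model's variation between cells, and no variation between animals.

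Cell classes were those the authors deposited. Naive progenitors (RPCs) and neurogenic progenitors were combined as progenitors and also described separately. Postmitotic classes were described where both libraries held at least 100 cells. Levels are summed UMIs per 10000 recovered UMIs of the class, with exact Poisson 95% intervals. Shares of cells have exact Clopper-Pearson binomial 95% intervals, and ratios (cTG over control) have exact conditional binomial 95% intervals. All these intervals cover counting error only, and none covers the difference between animals or preparations. No test between genotypes was made and no p-value is given, because cells are not replicates.

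The genes named were set by a rule fixed before the data were examined. Foxp1 and Jarid2 were always named. In progenitors the 12 largest and 12 smallest ratios were taken among genes with at least 100 UMIs, a ratio of at least 1.5 either way and an interval that excluded 1. In each postmitotic class the 4 largest and 4 smallest were taken by the same rule. Mitochondrial, ribosomal protein, hemoglobin and crystallin genes, Xist, Tsix and unnamed gene models were left out of these ranks. Members of 19 gene lists, fixed at the same time, could be named with at least 30 UMIs. Of each list the median log2 ratio of such members is given, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a test. Histones as a group, described in the closing observations, were chosen after their values were seen.

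No cell cycle phase was used from the deposited tables. Phases were scored with scanpy 1.11.5 from the fixed lists, of which 17 S phase genes and 7 G2/M genes had recovered counts. For comparisons at equal depth each cell was thinned to 534 UMIs, which left out 919 control cells and 542 cTG cells. Own clusters were made without Foxp1 from 2000 variable genes, 30 principal components and 15 neighbours, with leidenalg 0.10.2 at resolution 1. Cre was not kept out. The 23 clusters were named from the fixed markers in 2 ways, first by the mean z-score of the markers and, after those names had been seen, by their mean log2 fold. Both namings are reported, since they gave different shares. Doublet calls were those deposited, and cells called doublets were kept except in an added alternative. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Gene coordinates are from GENCODE M21 on the GRCm38 assembly, which is the assembly mm10 denotes.

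Alternatives fixed before the data were examined were median-of-ratios scaling, cells weighted alike, thinning, other UMI minimums, another total, G1 or cycling cells alone, own clusters, other denominators for the shares, and removal of the deepest or shallowest cells. Alternatives added afterwards were removal of doublet calls, the mean residual in place of the UMI ratio, the second naming of clusters, and lists without members at the limit or without ganglion cell transcripts.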

Results

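The recovered UMIs came from 4612 control cells and 3382 Foxp1 cTG cells. The median cell held 811.5 UMIs and 352.0 genes in the control library and 823.0 UMIs and 350.0 genes in the cTG library, counted over the recovered genes. Of the mitochondrial genes, mt-Nd3 in progenitors stood at 58.7 per 10000 in control and 65.5 in cTG. Progenitors were equally close in depth, with medians of 789.5 and 793.0 UMIs. Cones were not, with 1163 UMIs in control and 688.5 in cTG. DoubletFinder calls marked 28.7% of control cones and 23.1% of control rods, against 4.21% and 9.45% in the cTG library.

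The first question was whether the conditional transgene could be seen in the cells it was meant for. Cre, the recombinase expressed under Six3 control, had 1203 UMIs in cTG progenitors (6.58 per 10000) and 0 UMIs in control progenitors, which puts it at least 640-fold higher against a floor of 3 UMIs over the group. In RPCs 39.3% of cTG cells held a Cre UMI and 0 of 2583 control cells did. The cTG share was 50.0% in ganglion cells, 34.1% in neurogenic progenitors, 29.7% in photoreceptor precursors, 26.4% in rods and 22.1% in cones. It was 15.1% in amacrine cells and 57.1% in the 14 glia, and none of the 7 horizontal cells held one. Such shares depend on depth, with a median of 3253.5 UMIs in ganglion cells and 1926.5 in glia against 801.5 in RPCs. Per 10000 UMIs Cre stood at 3.17 in ganglion cells, 5.68 in glia and 6.89 in RPCs. No background share of Cre in the cTG library was measured. Foxp1, a forkhead transcription factor of early retinal progenitors, was at a like UMI level in the progenitors of both libraries. It stood at 4.998 per 10000 in control (1459 UMIs) and 5.37 in cTG (981 UMIs), a ratio of 1.07 (0.989 to 1.16). Foxp1 was lower in cTG photoreceptor precursors, with 2.44 against 4.89 (ratio 0.498, 0.355 to 0.692), in amacrine cells (ratio 0.798, 0.692 to 0.919) and in rods (ratio 0.734, 0.566 to 0.9503). Foxp1 lies on chromosome 6 from 98925338 to 99522721 on the minus strand, and the UMIs count 3' ends. A 3' count checks the transgene only if its transcript carries the counted part of Foxp1, which was not given in the sources used here. Weighting cells alike put the progenitor ratio at 0.975, and thinning put that of photoreceptor precursors at 0.759. Jarid2, the Polycomb cofactor named in the series title, had ratios of 1.05 (0.923 to 1.19) in progenitors, 0.777 (0.582 to 1.03) in neurogenic progenitors, 1.38 (1.06 to 1.81) in cones and 1.251 (1.03 to 1.52) in rods.

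The next comparison was of the makeup of the retina. Retinal ganglion cells, the first neurons born in the retina, made up 3.55% of cTG cells (120 cells, 2.95 to 4.23) and 0.195% of control cells (9 cells, 0.0893 to 0.370), a ratio of 18.2 (9.26 to 40.7). Amacrine cells held 17.3% of cTG cells (16.01 to 18.6) and 11.9% of control cells (10.98 to 12.9). Photoreceptor precursors held 8.96% and 6.57%, rods 5.94% and 4.79%, and cones 5.62% and 4.68%. Progenitors made up the rest of the difference, with 58.0% of cTG cells (56.4 to 59.7) and 71.7% of control cells (70.4 to 73.0). Among them RPCs held 44.6% and 56.0%, and neurogenic progenitors 13.5% and 15.7%. Glia were 14 cTG cells and 2 control cells, and horizontal cells were 7 and 6. The 10 genes of highest fold in the ganglion cell class included Nrn1, Thy1, Pou4f3, Pou4f2 and Pou4f1, and the 9 control cells all held Pou4f1 UMIs. These shares must sum to a whole. With postmitotic neurons alone as denominator the ratio was 0.987 for amacrine cells, 0.928 for photoreceptor precursors, 0.844 for rods and 0.816 for cones. Own clustering turned the direction for photoreceptor precursors (ratio 0.987). It named rods, however, a cluster of 247 control and 282 cTG cells, of which 56.3% were deposited photoreceptor precursors. The turn may therefore come from the naming.

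**Figure D1:**
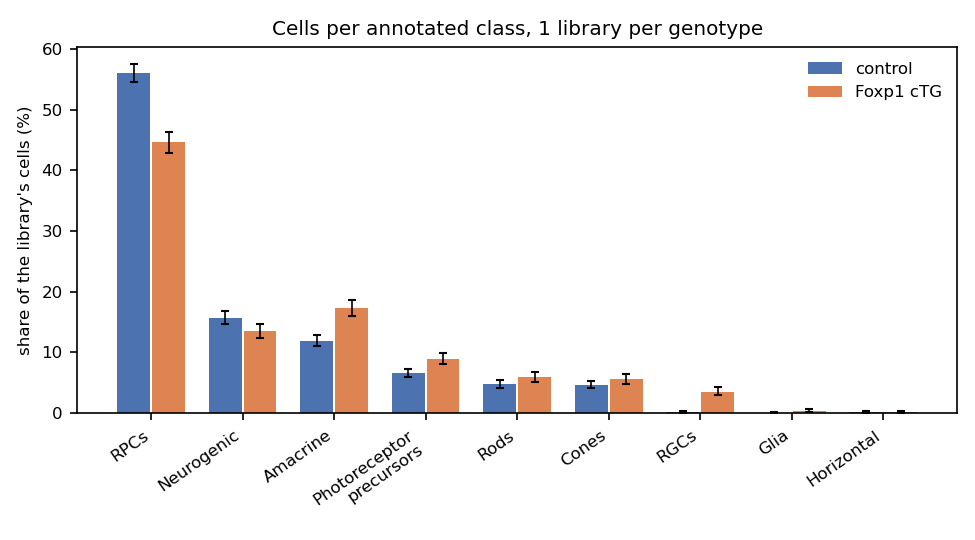
Bars give the share of each library's cells (y axis, percent) in each annotated class (x axis), with control in blue and Foxp1 cTG in orange, 1 library each. Error bars are exact binomial 95% intervals and cover counting error only. RPCs stood at 56.0% in control and 44.6% in cTG, and ganglion cells at 0.195% and 3.55%.

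Gene levels were then compared within progenitors, where Six3-Cre acts and where the series title places temporal progression. Some early progenitor genes were higher in the cTG library. Sfrp2, a secreted Wnt modulator, stood at 10.3 per 10000 in cTG and 3.89 in control (ratio 2.66, 2.47 to 2.86). Fgf15, a growth factor of early progenitors, stood at 37.5 and 23.3 (ratio 1.61, 1.56 to 1.67), Fgf3 had a ratio of 1.70 (1.49 to 1.93) and Hmga2, a chromatin protein of young progenitors, 1.62 (1.44 to 1.83). Several immediate early genes were far lower in cTG. Egr1 stood at 5.58 per 10000 against 44.1 in control (7.91-fold lower), Fos at 4.04 against 16.6 (4.12-fold lower) and Junb at 2.31 against 10.7 (4.65-fold lower). Car2, which encodes a carbonic anhydrase, stood at 3.33 against 15.6 (4.69-fold lower).

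Of the 16 measured members of the early progenitor list, 12 had a ratio above 1 and 4 were at least 1.5-fold higher with an interval above 1, while none was as much lower. The list's median log2 ratio was 0.23, at the 97.8 percentile of matched random lists. In RPCs alone 9 of 15 were above 1 and the median was 0.14, at the 81.4 percentile, and in neurogenic progenitors 0.18, at the 92.2 percentile. The 23 measured late progenitor genes went both ways, with a median of 0.04 at the 81.2 percentile. Among them Rlbp1 (ratio 2.01, 1.85 to 2.18), Hes5 (1.71, 1.65 to 1.77) and Slc1a3 (1.52, 1.46 to 1.59) were higher in cTG. Car2 (0.213, 0.196 to 0.232) and Gpr37 (0.461, 0.386 to 0.549) were lower. Nfia (1.03), Nfib (0.834) and Nfix (1.12), transcription factors of late progenitors, differed by less than 1.5-fold. Own clusters split part of the RPCs by library. One cluster held 523 cTG cells and 8 control cells and another 851 control cells and 92 cTG cells, while others were shared, such as one of 470 cTG and 288 control cells. Cre was among the top 10 genes of the first. Those of the second held Egr1 and Egr2, but also the histone genes Hist1h1a, Hist1h2ac, Hist1h3b, Hist1h2bn, Hist1h4d and Hist1h2an. The top 10 genes of the shared cluster were all histone genes, Hist1h4f, Hist1h3g and Hist1h2bl first. Cre was not kept out of the clustering, so the split may be partly built in.

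The 12 genes with the largest ratios were Cre, Sncg, Calb2, Ccnd2, Ly6h, Adamts18, Cyp2j6, Hist1h2bl, Chrna4, Nefl, Sfrp2 and Stmn4. Sncg (ratio 6.88, 4.89 to 9.87), Calb2 (5.53, 3.92 to 7.96) and Nefl (2.67, 1.81 to 3.996) are abundant in ganglion cells, and Sncg stood at 34.6 per 10000 in cTG ganglion cells, a lower bound. Sncg was also higher in cTG rods, where 7.96% of cells held a UMI against 1.36% in control, close to the 6.83% and 0.968% in RPCs. Median depths were 899.0 and 923.0 UMIs in rods and 801.5 and 821.0 in RPCs, cTG first. The Sncg difference is therefore not read as expression by progenitors. Nefl had a ratio of 2.49 in RPCs but 0.998 in rods, where 4.48% of cTG and 4.07% of control cells held a UMI, and 0.833 in amacrine cells. In cones its ratio was 5.86 (1.63 to 31.8), from 14 cTG and 3 control UMIs, and in photoreceptor precursors 1.52 (0.440 to 5.92). Ccnd2, a D-type cyclin, stood at 1.498 against 0.329 (ratio 4.56, 3.599 to 5.81), and Cyp2j6 at 4.10 against 1.19 (ratio 3.46, 3.04 to 3.94). The 12 genes with the smallest ratios were Slc15a2, Egr1, Mgat4c, Cxcl16, Pmaip1, Egr2, Cldn5, Car2, Junb, Fos, C1ql4 and Prss56. Slc15a2, a peptide transporter gene, had 166 UMIs in control and 3 in cTG (ratio 0.0289, 5.890e-03 to 0.0858). Mgat4c had 99 and 10 UMIs. Pmaip1, a proapoptotic gene, stood at 0.0820 against 0.411 per 10000. Cldn5, an endothelial tight junction gene, had a level at the limit in more than 5% of its cells.

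**Figure D2:**
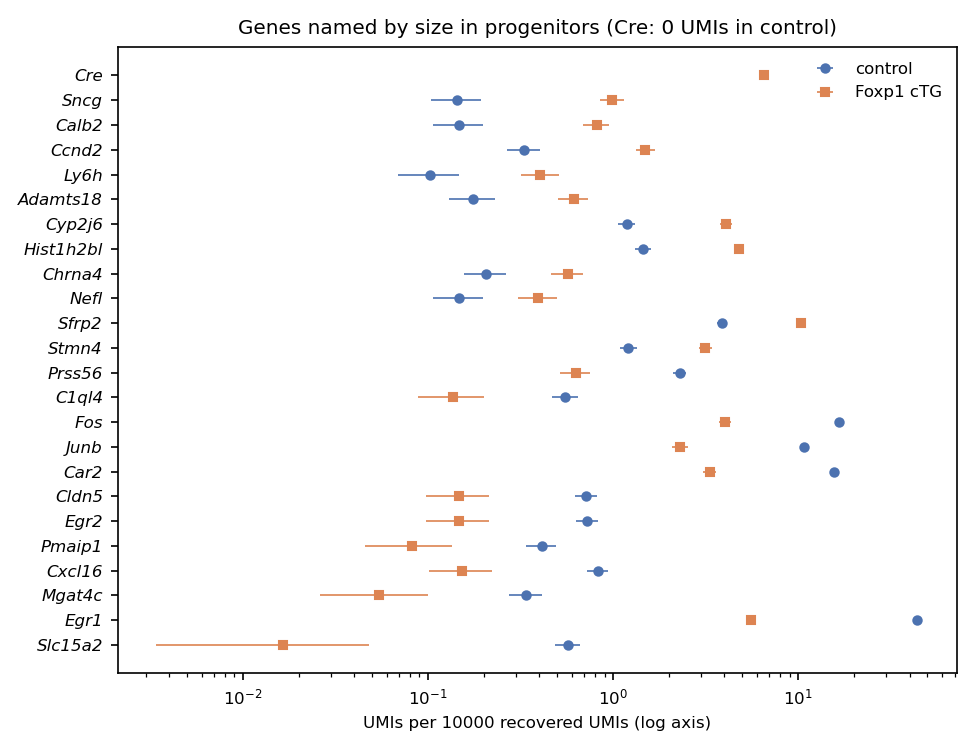
Points give the level of each gene named by size in progenitors (x axis, UMIs per 10000 recovered UMIs, log axis), blue circles for control and orange squares for Foxp1 cTG, 1 library each. Bars are exact Poisson 95% intervals covering counting error only. Egr1 stood at 44.1 in control and 5.58 in cTG, and Sfrp2 at 3.89 and 10.3.

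The dissociation and stress list stood lowest of the lists with more than 2 measured members, with a median log2 ratio of -0.93 over 15 measured members. None of the 10000 random lists had a median as low (percentile 0.00). Of these, 10 were at least 1.5-fold lower in cTG with an interval below 1, 2 were higher and 3 were neither. The 2 higher members were the heat shock genes Hspa1a (ratio 1.81, 1.53 to 2.15) and Hspa1b (1.76, 1.41 to 2.21), both lower-bound levels. Ier2 stood at 12.3 against 35.4 per 10000 and Gadd45b at 3.38 against 6.85. The ganglion cell list had a median of 0.53 over 17 members (99.9 percentile), with 7 at least 1.5-fold higher and 1 as much lower. Gap43, a growth cone protein gene, had a ratio of 2.12 (1.81 to 2.48), Stmn2 1.76 (1.63 to 1.91) and Nefm 0.627 (0.516 to 0.759). Without members at least 20-fold higher in cTG ganglion cells than in cTG progenitors, this list's median was 0.13.

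Notch pathway genes had a median of 0.38 over 6 members (99.1 percentile), led by Hes5, with Rbpj at a ratio of 1.33 (1.26 to 1.40) and Hes1 at 0.948 (0.916 to 0.981). The 12 neurogenic bHLH and Notch ligand genes had a median of 3.620e-03 (46.8 percentile), with Gadd45a at 0.514 the only one at least 1.5-fold apart. Atoh7 and Neurog2, neurogenic factors, had no recovered counts. Their mean residuals in neurogenic progenitors were 3.75 (SD over cells 6.17) and 3.06 (SD 4.89) in control and 5.98 (SD 6.78) and 5.51 (SD 6.01) in cTG. In RPCs they were -1.08 and -0.879 in control and -1.01 and -0.776 in cTG. Retinal progenitor transcription factors had a median of 0.19 (96.0 percentile), with Sox2 at 1.46 (1.40 to 1.52) and Lhx2 at 0.672 (0.645 to 0.700). The forkhead family had a median of -0.13 (11.3 percentile), with Foxp2 at 0.338 (0.283 to 0.403). The PRC2 and Jarid2 list, with 3 members measured, stood at 0.07 (49.7 percentile) and Ezh2 at a ratio of 0.901. Hedgehog and Wnt genes stood at 0.19 (86.4 percentile) over 4 members, and dorsoventral and nasotemporal patterning genes at 0.06 (51.8 percentile) over 9. Cone genes stood at 0.45 (93.4 percentile), rod and photoreceptor genes at 0.24 (88.6 percentile), bipolar genes at 0.20 (85.5 percentile) and amacrine and horizontal genes at -0.16 (5.92 percentile). With cells weighted alike the neurogenic bHLH, rod and bipolar medians lay below 0, as did the PRC2 and patterning medians in G1 cells alone. Without the top 5% of UMIs the cone median was 0.0312. Of the apoptosis list only Bbc3 and Pmaip1 were measured, with ratios of 1.32 (1.00 to 1.72) and 0.199 (0.108 to 0.342).

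**Figure D3:**
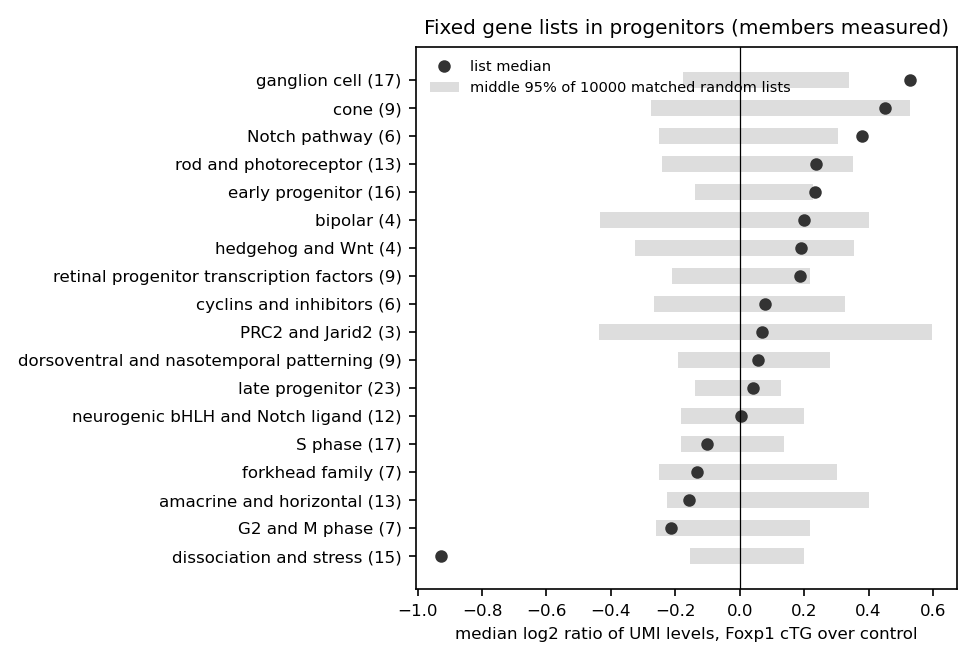
Points give the median log2 ratio of UMI levels, Foxp1 cTG over control (x axis), of each fixed list in progenitors (y axis, with the number of members measured). Grey bars span the middle 95% of 10000 random lists matched on expression. The dissociation and stress list stood at -0.93 and the ganglion cell list at 0.53.

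Progenitors of both libraries were mostly in S or G2/M by score. The G2/M share was 31.9% in cTG (29.9 to 34.1) and 37.2% in control (35.6 to 38.9). The S share was 54.3% and 52.2%, and the G1 share 13.8% and 10.6%. After thinning the G2/M share was 33.5% in cTG and 40.3% in control. All 7 measured G2/M genes had ratios below 1, with a median log2 ratio of -0.21 (6.72 percentile), Tacc3 at 0.744 (0.694 to 0.797) and Cdk1 at 0.775. Of 15 G2/M genes without recovered counts, 12 had a higher mean residual in cTG progenitors and 3 a lower one, with differences from -0.147 to 0.317 (median 0.102). Residuals had the covariate related to the cycle removed and recovered counts did not, so these directions cannot be set against those of the 7 measured genes. The 17 S phase genes had a median of -0.10 (15.5 percentile), and the cyclins and inhibitors 0.08 (57.4 percentile), with Cdkn1a at 0.522 (0.472 to 0.576). The deposited values had a covariate related to the cycle removed, whose median in progenitors was 0.0803 in control and 0.287 in cTG, and Top2a, Mki67, Ccnd1 and other cycle genes had no recovered counts, so these phases rest on few genes.

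In cones, rods and photoreceptor precursors Egr1 and Car2 were again among the 4 smallest ratios. Egr1 was lower in cTG cones (6.41 against 27.8 per 10000), rods (8.36 against 31.3) and photoreceptor precursors (4.58 against 14.6). Car2 was lower in all 3 of these classes, with ratios of 0.371, 0.242 and 0.256. In cones the genes of highest ratio were Islr2 (2.24, 1.74 to 2.90), Cdc25c (2.15), Crabp2 (2.08) and Rprm (1.96). Thinning turned Crabp2 in cones to a ratio of 0.656, and put Car10 in amacrine cells at 1.47 and Enc1 in rods at 4.53. Without doublet calls the Egr1 ratio was 0.351 in cones and 0.473 in rods, and that of Cdc25c in cones was 9.99. Progenitor genes were seen in both classes. Lhx2 was in 58.8% of control and 36.8% of cTG cones, and in 53.4% and 43.8% of rods. Sox2 was in 46.8% and 30.5% of cones, and in 38.5% and 40.3% of rods. Levels in cones and rods may therefore not be those of photoreceptors alone. Photoreceptor precursors had Cre, Nrxn3 (2.38, 1.75 to 3.27), Onecut1 (2.10) and Zfhx4 (2.05) at the top. Rods had Slitrk6 (2.64, 1.79 to 3.97), Enc1 (2.52), Rian (2.05, or 1.24 without the top 5% of UMIs) and C2cd4b (2.05). Amacrine cells had Cre, Car10 (2.87), Cdh6 and Cbln2 at the top, the last at a ratio of 2.30 (1.796 to 2.96), and Slc15a2 (0.0437, thinned 8.849e-03), Mxd3 (0.201, or 0.364 without doublet calls), Npy (0.211, or 0.118 without the top 5% of UMIs) and Smpdl3a (0.238) at the bottom. The levels of Car10, Cdh6, Cbln2 and Npy, and of C2cd4b in rods, were lower bounds. The dissociation and stress list had a median below 0 in each of these 4 classes, from -0.36 in photoreceptor precursors to -0.87 in rods.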

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

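Of the tests below, those on ganglion cell transcripts, on handling, on heat shock and other stress genes, on exchanged labels and on the width of the Foxp1 interval were chosen after the result was seen. Each of the differences rests on 1 animal per genotype, so a difference between the 2 animals stays open throughout.

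Foxp1 stood on opposite sides of 1 in different classes. Its ratio was 1.10 in RPCs, and 0.798 in amacrine cells, 0.498 in photoreceptor precursors and 0.734 in rods, and the difference between classes was not tested. With cells weighted alike the RPC ratio was 0.992. Foxp1 UMIs were not clearly higher in cTG progenitors although the transgene was meant to act there. Exchanged labels would put Cre UMIs in the other library, but the cTG library held 1761 and the control library 0. Too few UMIs is argued against by the upper bound of the progenitor ratio, which was 1.16. Transgene transcripts may lack the counted 3' part of Foxp1. Foxp1 levels in cTG progenitors with a Cre UMI over those without had a ratio of 1.01 (0.890 to 1.15), which does not decide, because a cell without a Cre UMI need not lack Cre.

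Ganglion cells were 120 in the cTG library and 9 in control, the largest share ratio of the annotated classes. A cut on deep cells in the control library is argued against, since 1.06% of its other cells and 1.16% of the other cTG cells reached the median UMIs of ganglion cells. Misplacement of control ganglion cells in the annotation is argued against by own clustering, whose ganglion cell cluster held 9 control and 121 cTG cells. Outside the class 41 control cells held at least 5 ganglion cell markers, but so did 35 cTG cells. Equal shares would need 154 more control cells, so the count of 41 alone does not decide. Loss of control ganglion cells after dissociation, with their RNA kept in the suspension, would leave that RNA at a like level in both libraries. Loss before dissociation was not tested. Summed UMIs of 126 ganglion cell transcripts in progenitors had a ratio of 1.30 (1.26 to 1.34). Because that set held amacrine transcripts, a stricter set of 18 was drawn from it, with 1.35 (1.23 to 1.48). Most members of the stricter set stood above 1. Intervals lay above 1 for Sncg (6.88), Nefl, Nrn1, Pou4f2, Pou4f3, Chl1 and Slc18a2, several of them on few UMIs. Rbpms, with 53.6% of the control UMIs, had 0.757 and the only interval below 1, while Irx2 and Lrfn5 also had ratios below 1. Sncg and Rbpms were thus far from a like level. The set's ratio was 2.03 (1.79 to 2.30) without Rbpms and 1.10 (0.991 to 1.21) without Sncg. The size of the summed ratio depends on Rbpms and Sncg, and progenitors may make some of these transcripts themselves, so loss and absence cannot be told apart.

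The dissociation and stress list had a median below 0 in all 6 classes described, from -1.09 to -0.36, and Egr1, Fos and Junb were lower in cTG in each, while Jun was higher in photoreceptor precursors (ratio 1.34), amacrine cells (1.13) and cones (1.11). Depth is argued against, since the summed ratio of Egr1, Fos and Junb in thinned progenitors was 0.165 (0.155 to 0.177), against 0.167 unthinned. General cell stress in the control preparation stays open, since Hspa1a and Hspa1b had a summed ratio of 1.79 (1.57 to 2.05), a lower-bound level, but Atf3, Ddit3 and Gadd45b one of 0.501 (0.475 to 0.529). The labels give 35 min of dissociation for both libraries. Another difference in handling, such as time before dissociation, may account for the pattern, and so could the genotype. The direction in 6 of 6 classes goes with both, because Six3-Cre marks the lineage of all of them and each genotype was 1 preparation, so they cannot be told apart.

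Doublet calls, a deposited column used here only to describe the classes and in an added alternative, marked 2.04% of cTG progenitors and 0.938% of control progenitors.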

How the results depend on the processing

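Of 600 recomputed values over 101 results, 524 counted as staying, 63 as moving outside the interval of the reported value and 13 as changing side. A change of side was counted only where the reported interval excluded no difference. Other crossings counted as staying or moving, such as that of the progenitor Foxp1 ratio with cells weighted alike. Differences in mean residual were judged by direction only and not against an interval. For Jarid2 and the genes named by size in progenitors except Cre, 166 of 168 stayed and none changed side in this sense. Jarid2 had a progenitor ratio of 1.05 but a slightly lower mean residual in cTG (difference -1.561e-03). The doublet removal, the second naming of clusters, the residual difference and the lists without lower-bound or ganglion cell members were chosen after seeing the data. Ganglion cells kept their direction under every alternative run. Causes were not tested unless stated.

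With cells weighted alike, the Foxp1 ratio was 0.975 in progenitors and 0.992 in RPCs, the neurogenic bHLH median -0.11, the rod and photoreceptor median -4.983e-03 and the bipolar median -6.138e-03. Thinning gave Crabp2 in cones 0.656. Median-of-ratios scaling gave the late progenitor list 6.770e-03. S and G2/M cells alone gave the early progenitor list 0.14 and the G2/M list -0.16. G1 cells alone gave S phase -0.38, G2/M -1.30, neurogenic bHLH -0.17, stress -0.77, apoptosis 6.400e-03, rod and photoreceptor -0.0924 and bipolar -0.0545. They also gave Notch 0.07, PRC2 -0.23, forkhead -0.54, cyclins 0.51, hedgehog and Wnt 0.26, patterning -0.26 and progenitor factors 0.27. G1 is called from low S and G2/M genes, so the S and G2/M medians are partly built in. Without the top 5% of UMIs the rod and photoreceptor median was -0.0291 and the cone median 0.0312. Without ganglion cell transcripts the ganglion cell list stood at 0.13.

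Own clusters named by z-score gave share ratios of 0.889 for progenitors, 0.900 for RPCs, 1.78 for amacrine cells and 0.987 for photoreceptor precursors. Named by fold, the same clusters gave 1.35 for amacrine cells and 0.987 for photoreceptor precursors. They gave 0.601 for progenitors and 0.539 for RPCs, because a cluster of 523 cTG and 8 control cells was then called Muller glia and one of 228 control and 143 cTG cells stayed unnamed. The first naming matched the deposited class of 78.8% of cells and the second 69.9%, so the size of the progenitor difference depends on naming. Among postmitotic neurons only, the ratios were 0.987 for amacrine cells, 0.928 for photoreceptor precursors, 0.816 for cones and 0.844 for rods. Without doublet calls the cone ratio was 1.60. After thinning, the control G1 share was 8.99%, its G2/M share 40.3% and the cTG S share 51.5%. Within progenitors the medians were 789.5 UMIs and 347.0 genes in control and 793.0 and 345.0 in cTG. With a minimum of 30 UMIs the rule for named genes kept 14 of 24. No paired analysis was possible because each group had 1 library and the result comes from no test.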

Other observations

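Histone genes with symbols that begin with Hist, a group chosen after its values were seen, went both ways in progenitors. Of 41 measured, 1 was at least 1.5-fold higher in cTG, 4 were as much lower and 36 were neither, with a median log2 ratio of -0.08. Hist1h2bl stood at 4.80 per 10000 in cTG and 1.45 in control (ratio 3.30, 2.94 to 3.72), while Hist1h2ac stood at 5.27 and 9.92 (ratio 0.531) and Hist1h1a at 4.51 and 8.12 (ratio 0.556).

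Among genes with at least 100 UMIs in neurogenic progenitors, those of highest ratio after Cre were Mab21l1, Bcl11a and Reln. Mab21l1 had a ratio of 2.73 (1.86 to 4.05), Bcl11a 2.60 (1.86 to 3.65) and Gad2, which makes the transmitter GABA, 2.39 (1.90 to 3.003). Reln, an extracellular matrix protein gene, stood at 1.87 against 0.745 per 10000. Sfrp2 had a ratio of 2.33 (1.75 to 3.12) and Penk 2.23 (1.83 to 2.71). Cells with at least 2 astrocyte markers were 11 in the cTG library and 1 in control, and cells with at least 2 microglia markers were 3 and 2. Cells with at least 2 endothelium and pericyte markers were 98 (2.90%) and 240 (5.20%), but 1 of these markers, Kdr, was in 58.1% of all control cells, so this count is not one of endothelial cells.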
